A study of Homo sapiens with 32 samples.

How the data were processed

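RNA sequencing of TET21 cells, a human neuroblastoma line, was analysed from 32 libraries in 8 groups of 4: empty vector (EV), full-length MYC (WT) and the MYC deletion mutants d0x, d1, d2, d3a, d3b and d4. Groups were taken from the labels, and the mutants are named ΔMB0, ΔMBI, ΔMBII, ΔMBIIIa, ΔMBIIIb and ΔMBIV after the MYC boxes, an assignment inferred from the label names.

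The authors deposited 2 tables of their own comparisons, with 58317 genes in the first and the 9368 genes given a MYC binding site in the second. Per the file headers, each comparison has a log2 posterior fold change between its groups and a posterior probability of differential expression (PPDE), from a Bayesian model of read counts, and a gene whose read counts were 0 has no value. Per the file headers, a PPDE of at least 0.95 is a call and equals a false discovery rate below 0.05. The number of comparisons called per gene, as deposited, equalled the count of PPDE values of at least 0.95 for all 58317 genes. The submitters' processing notes list STAR 2.5.2a, edgeR 3.16.5, R 3.3.1, DESeq and the build GRCh37, without saying which program gave the posterior values or how libraries were scaled. How binding sites were assigned to genes is not stated either, and binding was mapped in 1 experiment. The folds of bound genes differ between the 2 tables, so each table appears to come from its own fit, and values are taken from the first unless the second is named.

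Since values per library, depths, standard errors and unadjusted p-values were not used here, a test on counts, a leave-one-out analysis and a gene set test that uses the correlation between genes were not run, and the precision of a single fold is unknown. The comparisons used were WT against EV and each of the 6 mutants against WT. Comparisons of mutants with EV were not analysed here, except that the sum of the ΔMBIV and the WT against EV fold stands for ΔMBIV against EV in 1 test.

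A gene counted as tested where the authors' table gave a fold and a PPDE, which held for 42605 genes in at least 1 comparison. Gene types came from GENCODE 29 on GRCh38, matched by symbol, which found 28028 tested genes, 17168 of them protein coding, and 92.4% of called genes. GENCODE was also used for which genes neighbour each other, and its coordinates were not set beside values on GRCh37.

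Gene lists, the naming rule and the comparisons were chosen before the data were examined. The 28 lists cover the MYC network, ribosome biogenesis and nucleolus, ribosomal proteins, translation factors and tRNA synthetases, nucleotide and polyamine synthesis, glycolysis, glutamine and one-carbon metabolism, mitochondrial biogenesis and chaperones, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and growth arrest, extracellular matrix, cell adhesion, actin cytoskeleton and SRF/YAP targets, interferon response, antigen presentation, cytokines and NF-kB targets, p53 targets, ATF4 and the unfolded protein response, cholesterol synthesis, lysosome and autophagy, circadian clock, MYC cofactors, adrenergic and mesenchymal neuroblastoma, Schwann and neural crest, immune cells, epithelial cells, and histone and mitochondrial genes as a sign of RNA quality. Risen and fallen members were each compared with all other tested genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 56 tests of a comparison. Genes of a list are not independent replicates. Named were MYC, the 10 risen and 10 fallen called genes with the largest folds in WT against EV, 5 and 5 in each mutant, leaving out symbols that start with LOC or LINC, or with RP, AC or AP and digits, and up to 4 members per list with the highest PPDE.

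Bound and unbound genes were compared in the same way, over 14 tests. The similarity of a mutant to WT was the slope of its fold on the WT against EV fold, over all tested genes as planned. On simulated data of 37690 genes the slope, after subtraction of a reference mutant, missed known losses by up to 0.145, whereas the median share of the WT change lost recovered them within 0.0132 after the same subtraction and within 0.0122 without it, so that the median share over genes called in WT against EV was added. Its intervals are 95% intervals from 1000 resamples of genes with seed 7. The simulation took each gene's noise from its ΔMBIIIb fold and called genes with that noise known. The noise is not known in the data, so errors there may be larger. For a simulated mutant that lost none of a planted WT effect, with shared WT libraries, the correlation with WT against EV across all genes was -0.463. In the same simulation 4% of random lists had a p below 0.05, and 8 of 8 planted lists were recovered.

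Alternatives were a PPDE of 0.90 or 0.99, an absolute log2 fold of at least 1, protein-coding genes alone, the authors' fit of bound genes, subtraction of the ΔMBIIIb fold, bound genes alone, and folds centred on the median protein-coding gene. Work was done in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.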

Results

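RNA was sequenced from TET21 cells, a human neuroblastoma line derived from SH-EP cells that carries a MYCN transgene which doxycycline switches off. The 32 libraries fall into 8 groups of 4: an empty vector (EV), full-length MYC (WT), and MYC lacking a short conserved segment, in mutants labelled d0x, d1, d2, d3a, d3b and d4. The labels do not describe the segments. From the label names and general knowledge of MYC they were taken to be the MYC boxes, and the mutants are called ΔMB0, ΔMBI, ΔMBII, ΔMBIIIa, ΔMBIIIb and ΔMBIV here. Per the labels' protocol, cells received doxycycline at 1 µg/mL for 7 days before harvest. What was analysed is the authors' deposited table of their own 7 comparisons, WT against EV and each mutant against WT, with a log2 fold and a posterior probability of differential expression (PPDE) per gene. A gene is called here, and said to have risen or fallen, where its PPDE is at least 0.95, the authors' threshold for a false discovery rate of 0.05. Between 37690 and 38271 genes had values in each comparison. Values per library, depths and standard errors were not used here, so single folds are printed with no SD. Replicate numbers run from 4 to 7 in every group, and the labels do not say whether they are separate cultures, so the calls may measure technical spread only.

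The targeted gene comes first. In the authors' deposited table the log2 fold of MYC was 0.98 in WT against EV, with a PPDE of 0.348, so that MYC itself was not called. Against WT, the same table put MYC at 0.57 in ΔMB0, 0.46 in ΔMBI, 0.68 in ΔMBII, 0.67 in ΔMBIIIa, -0.09 in ΔMBIIIb and 0.57 in ΔMBIV, and called it in none of these. A fold over the whole gene includes the cells' own MYC and does not show the deletions. MYCN stood at -0.38 in WT against EV in the authors' deposited table and was not called.

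WT against EV asks what full-length MYC changes in these cells. Members of the ribosome biogenesis, mitochondrial and nucleotide synthesis lists rose, and members of the extracellular matrix, adhesion and actin cytoskeleton lists fell. The authors' deposited table called 1876 genes, of which 754 rose and 1122 fell, with a median absolute log2 fold of 0.73. The largest rises in the authors' deposited table were those of NPTX1 (5.34), a secreted neuronal pentraxin, GALNT18 (4.58), the chemokine CCL5 (4.52), the sarcomeric actinin ACTN2 (3.69), PLCXD3 (3.33) and RGS16 (3.25), a GTPase activator that acts on G proteins. HSD11B1, which regenerates cortisol, followed at 3.19, the growth factor BMP2 at 2.92, NAT8L at 2.65 and the acute-phase gene SAA1 at 2.56 in the authors' deposited table. Among the deepest falls in the authors' deposited table were those of SERPINB2 (-8.71) and CCND2 (-7.04), a D-type cyclin. SLFN11 stood at -6.35, the desmosomal cadherin DSG2 at -6.28 and FAM83A at -6.17 in the authors' deposited table. The granzyme inhibitor SERPINB9, the epithelial transcription factor EHF, the gap junction gene GJB2 and FAM110C fell too, but have no value in some comparisons of a mutant with WT, which the table gives to genes with no reads. WT therefore held no or almost no reads of these 4 genes, and their folds, which depend on the model, are not given. Few reads may not be limited to them. FAM83A shared its exact ΔMBII fold of 0.88 with other deeply fallen genes, so its own fold may depend on the model too.

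**Figure D1:**
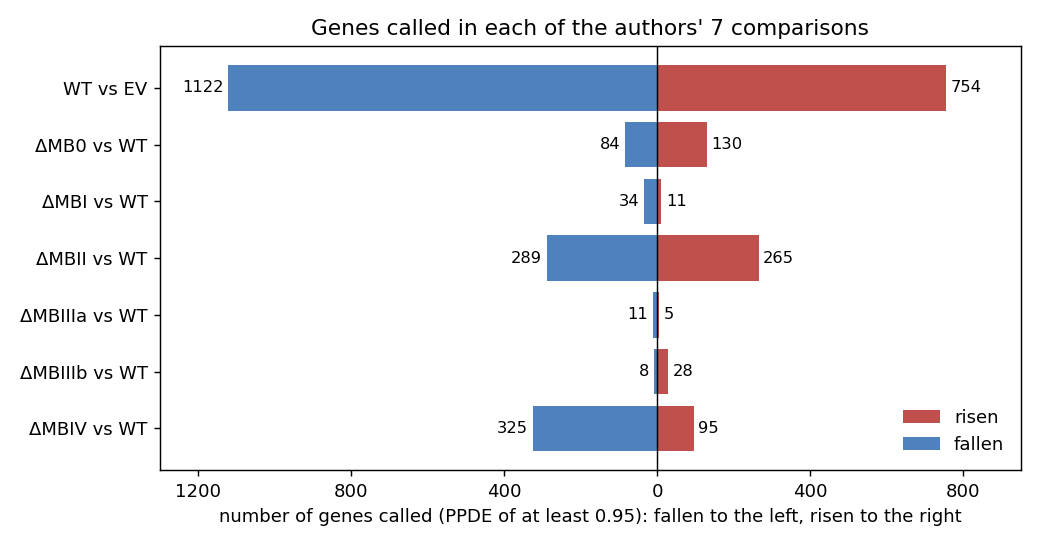
Number of genes called (PPDE of at least 0.95) in each of the authors' 7 comparisons, fallen genes to the left and risen genes to the right of 0. WT against EV has 754 risen and 1122 fallen genes, ΔMBII 265 and 289, ΔMBIV 95 and 325, and ΔMBIIIa the fewest, with 5 and 11.

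Of 36 measured genes of ribosome biogenesis and the nucleolus, 15 rose and none fell (adjusted p = 2.47e-15, two-sided Fisher's exact test against all other tested genes). Examples in the authors' deposited table are RRP1B at 0.92, NOP56 at 0.62, NOP16 at 0.70 and NOLC1 at 0.65. Among nucleotide and polyamine synthesis genes 6 of 25 rose (adjusted p = 8.33e-05), with ODC1, the entry enzyme of polyamine synthesis, at 0.76 and UMPS, which makes UMP, at 0.50 in the authors' deposited table. Mitochondrial biogenesis and chaperone genes rose in 5 of 24 cases (adjusted p = 7.35e-04), led in the authors' deposited table by GRPEL1 at 0.70, C1QBP at 0.71 and the coactivator PPARGC1B at 1.67. In the list of G1/S and DNA replication genes 6 of 28 rose (adjusted p = 1.40e-04), among them CCNE1 at 0.78 and CDC25A at 0.76 in the authors' deposited table, while CCND2 was its only fallen member. Of 34 ribosomal protein genes 4 rose (adjusted p = 0.0188), with RPL9 at 0.44 and RPS6 at 0.33 in the authors' deposited table. That last result was lost against protein-coding genes alone (adjusted p = 0.165, Fisher's exact test), and reads of ribosomal proteins can be shared with pseudogenes. The G1/S result had an adjusted p of 0.0529 at a PPDE of 0.99. No member of the 24 genes of G2/M and mitosis was called, and their median log2 fold was -0.17.

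The extracellular matrix list had the most fallen members, 22 of 32 with none risen (adjusted p = 4.36e-25, Fisher's exact test) and a median log2 fold of -1.28. In the authors' deposited table the basement membrane collagen COL4A1 stood at -1.86, the matricellular SPARC at -1.41, THBS2 at -1.01, and COL3A1 at -1.23. Cell adhesion genes fell in 10 of 22 cases (adjusted p = 4.00e-09), led by the integrin ITGB3 at -1.75, the cadherin CDH11 at -1.81 and VCAM1 at -1.71 in the authors' deposited table. Of the actin cytoskeleton and SRF/YAP target genes 7 of 18 fell (adjusted p = 6.19e-06), with CYR61 at -1.24 and CTGF at -1.83, both known YAP targets, in the authors' deposited table. Interferon response genes fell in 6 of 28 cases (adjusted p = 9.57e-04), with STAT2 at -0.87 and IFI44 at -1.18, and 5 of 19 lysosome and autophagy genes fell (adjusted p = 1.11e-03), with WIPI1 at -0.88 and CTSB at -1.05 in the authors' deposited table. Of the CDK inhibitor and growth arrest list 5 of 22 fell and BTG2 alone rose (Fisher's exact test, adjusted p = 2.10e-03 for falls, and 0.0611 at a PPDE of 0.99). The fallen members were TXNIP at -1.18, KLF6 at -0.72, KLF2 at -1.69, GADD45B at -0.42 and CDKN2C at -0.34 in the authors' deposited table, of which only CDKN2C, named after its values were seen, encodes an inhibitor of cyclin-dependent kinases. The call of GADD45B ended in the authors' separate fit of MYC-bound genes.

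The ATF4 and unfolded protein response list had 4 of 17 members fallen (adjusted p = 6.59e-03), namely VLDLR, DDIT3, CHAC1 and ASNS at -1.32, -0.97, -1.90 and -0.77 in the authors' deposited table. The mesenchymal neuroblastoma list had 4 of 22 fallen (adjusted p = 0.0165), SNAI2, FOSL2, NOTCH2 and NOTCH3 (Fisher's exact test). NOTCH3, named after its values were seen, was not called in the separate fit of bound genes. The epithelial list, a marker set of another cell type, had 3 of 13 fallen (adjusted p = 0.0232), KRT5 at -5.10, KRT14 at -4.66 and CDH1 at -3.59 in the authors' deposited table. The simple-epithelium keratins KRT8 at -0.38 and KRT18 at -0.24 in the same table were not called. Against protein-coding genes alone the adjusted p was 0.0812 for the ATF4 list and 0.165 for each of the other 2, and at a PPDE of 0.99 it was 0.0611 for the mesenchymal and 0.144 for the epithelial list. None of 13 measured immune cell genes was called, and the RNA quality list of histone and mitochondrial genes had 1 called member of 18, MT-CO3 at 0.39 in the authors' deposited table. The adrenergic neuroblastoma list had 1 risen and 2 fallen of 22, and the Schwann and neural crest list 1 fallen of 15, ETS1. In the MYC network list MXI1 rose and MXD1 fell, at 1.01 and -0.63 in the authors' deposited table, among 13 genes. Cytokine and NF-kB genes included CCL5, risen, and IL6 and IL1B, fallen to -1.27 and -5.32 in the authors' deposited table. The lists of translation factors, glycolysis, antigen presentation, p53 targets, cholesterol synthesis, circadian clock and MYC cofactors had at most 2 called members each and did not pass.

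**Figure D2:**
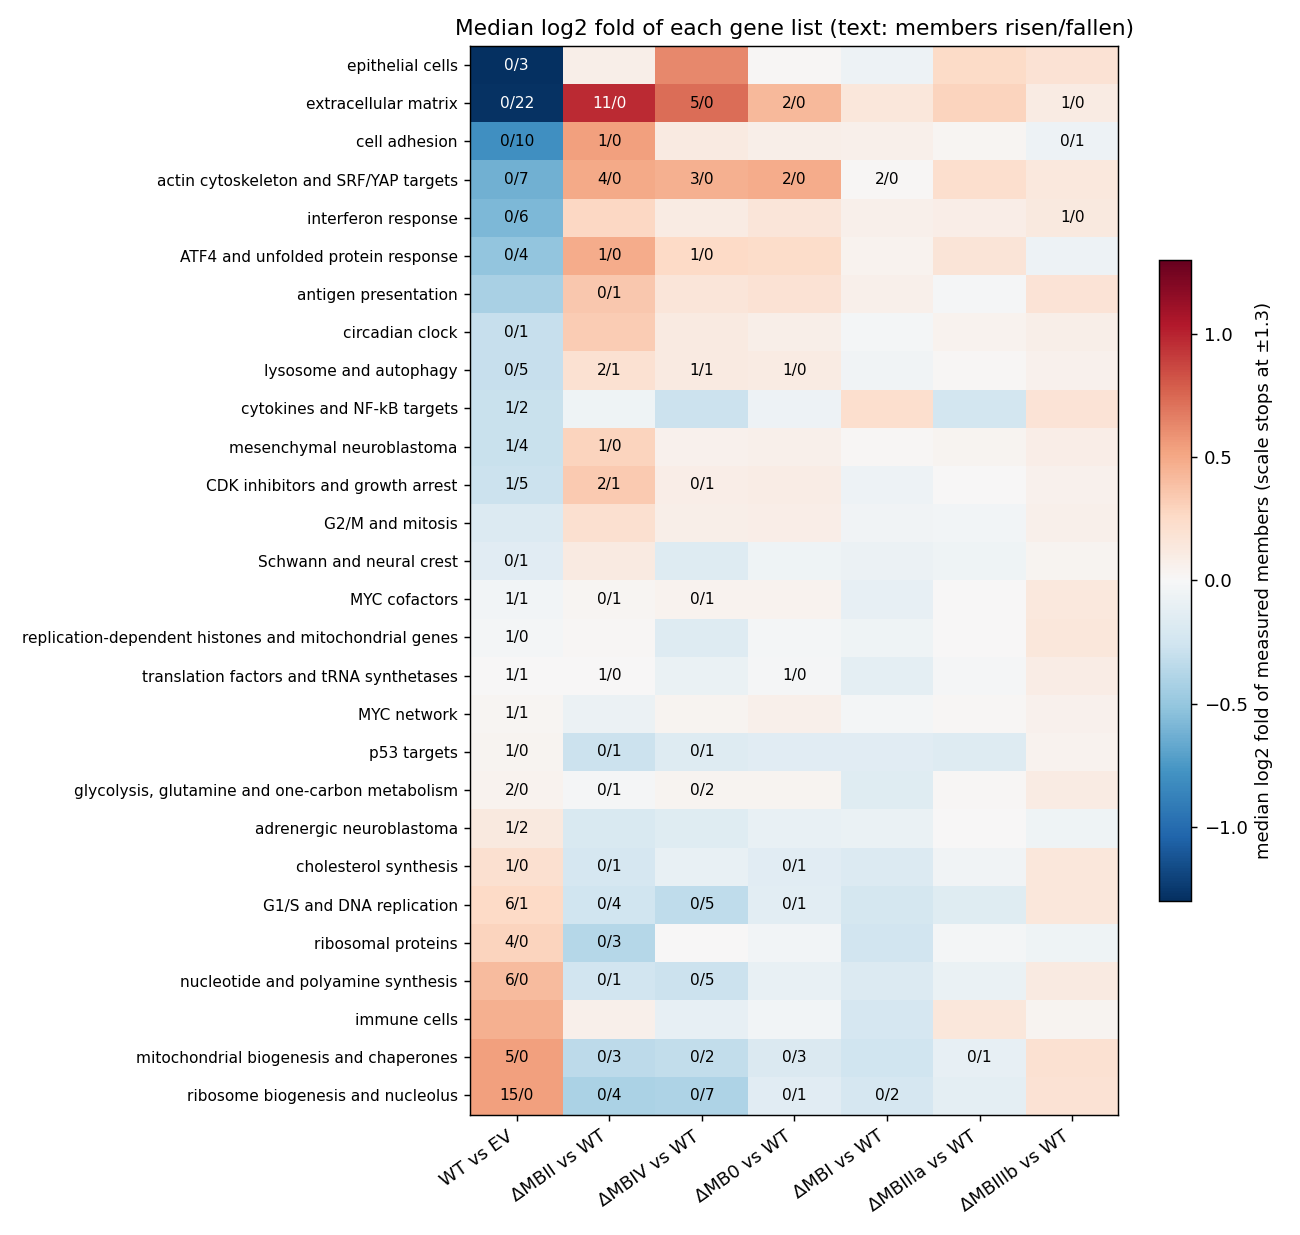
Median log2 fold of the measured members of each of the 28 gene lists (rows) in the 7 comparisons (columns), on a colour scale that stops at 1.3 in either direction. The pairs of numbers give members risen/fallen and are left out where no member was called. The extracellular matrix list has 0 risen and 22 fallen members in WT against EV and 11 risen and 0 fallen in ΔMBII against WT.

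Each mutant was compared with WT to see which of the WT changes differ with each deletion. Amounts of MYC protein were not available here, so a difference cannot be assigned to the box itself. ΔMBII had the most called genes, 554, with 265 risen and 289 fallen in the authors' deposited table. Members of the matrix list rose, and members of the ribosome biogenesis and the G1/S and DNA replication lists fell. The largest rises in the authors' deposited table were those of PTPRZ1 (5.82), a receptor tyrosine phosphatase, the membrane glycoprotein PDPN (3.27), IGFBP5 (2.52), which binds insulin-like growth factors, and the matrix protein NPNT (2.45). The neural adhesion molecule CHL1 rose as well, from no or almost no reads in WT, so that its fold is not given. The deepest falls in the authors' deposited table were those of NPTX1 (-4.42), RGS16 (-2.93), the phosphatase subunit PPP2R2C (-2.93), and the olfactory receptor genes OR51M1 (-2.83) and OR51I2 (-2.71), which have near copies beside them. Of 32 extracellular matrix genes 11 rose (adjusted p = 9.47e-15, Fisher's exact test), with SPARC at 1.13, THBS2 at 0.88, COL3A1 at 0.94 and fibronectin, FN1, at 1.77 in the authors' deposited table. Among genes that fell by at least 3 on the log2 scale in WT against EV, 49 of 59 stood above 0 in ΔMBII. Their median was 1.44, with 5 called. The epithelial list as a whole had a median of 0.08 and 0 called of 13. However, its 3 members that fell in WT against EV, KRT5, KRT14 and CDH1, stood at 3.18, 2.63 and 0.64 in ΔMBII. They were picked as low in the same WT libraries, so a rise is partly built in. Actin and SRF/YAP genes rose in 4 of 18 cases (adjusted p = 1.81e-04), CYR61 at 1.03, CTGF at 1.38, VCL at 0.30 and TPM1 at 0.51 in the authors' deposited table. Fallen were 4 of 36 ribosome biogenesis genes (adjusted p = 2.21e-03), RRP1B at -0.76, NOP56 at -0.64, NOP16 at -0.52 and NOLC1 at -0.53 in the authors' deposited table. Fallen as well were 4 of 28 G1/S genes (adjusted p = 1.07e-03), CCNE1 at -0.77, CDC25A at -0.81, MCM3 at -0.54 and MCM10 at -0.45 in the authors' deposited table. In the mitochondrial list 3 of 24 fell (adjusted p = 8.69e-03), GRPEL1, PPARGC1B and C1QBP at -0.72, -1.36 and -0.59 in the authors' deposited table, and among ribosomal proteins 3 of 34 (adjusted p = 0.0203), RPL14, RPS6 and RPL4. Against protein-coding genes the adjusted p of those last 2 lists was 0.0518 and 0.129, and no ribosomal protein gene was called at a PPDE of 0.99. In the separate fit of bound genes NOP16, MCM3, VCL, TPM1, RPL14 and RPL4 were not called.

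ΔMBIV had 420 called genes in the authors' deposited table, 95 risen and 325 fallen. Members of the ribosome biogenesis, nucleotide and polyamine synthesis and G1/S lists fell, and members of the matrix and actin lists rose. Among the largest rises in the authors' deposited table were those of the pseudogene OR5H3P (3.19), TMEM132B (2.73), VSTM2L (2.69) and the growth factor IGF2 (2.48). The deepest falls in the authors' deposited table were those of NPTX1 (-4.30), the protocadherin PCDHB5 (-3.47), the pseudogene RPL31P50 (-2.56), NOL4 (-1.79) and LONRF3 (-1.47). Of 36 ribosome biogenesis genes 7 fell (adjusted p = 6.13e-07), with RRP1B at -0.38, NIP7 at -0.54, NOP16 at -0.58 and NOP56 at -0.31 in the authors' deposited table. Nucleotide and polyamine genes fell in 5 of 25 cases (adjusted p = 3.92e-05), among them ODC1, UMPS, CTPS1 and RRM2 at -0.33, -0.35, -0.23 and -0.43 in the authors' deposited table. G1/S genes fell in 5 of 28 cases (adjusted p = 5.32e-05, and 0.768 at a PPDE of 0.99), with GINS1 at -0.33, GINS2 at -0.38, MCM10 at -0.35 and the replication clamp PCNA at -0.61 in the authors' deposited table. Rises were seen in 5 of 32 matrix genes (adjusted p = 6.13e-07), among them SPARC, TGFBI, THBS2 and TNC at 0.70, 0.73, 0.69 and 0.94 in the authors' deposited table. The epithelial list, of another cell type, had a median log2 fold of 0.63 in ΔMBIV with none of its 13 genes called, and of the 62 genes that fell by at least 3 on the log2 scale in WT against EV 60 stood above 0 in ΔMBIV, with a median of 1.97 and 3 called. These genes were chosen as low in WT, so a rise against the same WT libraries is partly built in. Besides ΔMBII and ΔMBIV, 50 of 60 stood above 0 in ΔMBIIIa and 48 of 60 in ΔMBI. In ΔMB0 it was 37 of 59 and in ΔMBIIIb 33 of 59, with 0 called in each of these. In the actin list 3 of 18 rose in ΔMBIV (adjusted p = 1.37e-04), CYR61, CTGF and ACTA2 at 0.60, 0.53 and 1.00 in the authors' deposited table. The ATF4 list had 1 risen member of 17, the glutathione-degrading enzyme CHAC1, at 1.71 in the authors' deposited table. In the separate fit of bound genes ODC1, CTPS1, NOP16, NOP56, GINS2, MCM10, LONRF3 and VSTM2L were not called.

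ΔMB0 had 214 called genes in the authors' deposited table, 130 risen and 84 fallen. The largest rises in the authors' deposited table were those of NAP1L6 (2.90), the lysosomal protease CTSF (1.61), FAM65B (1.59), FOXR2 (1.42) and the stress-response gene NUPR1 (1.25), and the deepest falls those of NPTX1 (-6.38), VAV3 (-3.86), PCDHB5 (-3.0), PPP2R2C (-2.02) and PLCXD3 (-1.77). Of the mitochondrial list 3 of 24 fell (adjusted p = 1.12e-03), GRPEL1, C1QBP and PPARGC1B at -0.28, -0.19 and -0.64 in the authors' deposited table. In the actin and SRF/YAP list CTGF and CYR61 rose, to 0.64 and 0.65 in the authors' deposited table, 2 of 18 members (adjusted p = 0.0473, and 0.185 against protein-coding genes). The matrix list had 2 risen members, among them COL4A1 at 0.95 in the authors' deposited table, and did not pass (adjusted p = 0.0992). VAV3 and C1QBP were not called in the separate fit of bound genes.

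ΔMBI had 45 called genes in the authors' deposited table, 11 risen and 34 fallen. The unannotated transcript CTD-2328D6.1 rose from no or almost no reads in WT, and its fold is not given. The other largest rises in the authors' deposited table were those of the growth factor EREG (0.73), VEPH1 (0.54), the checkpoint ligand PDCD1LG2 (0.52) and the ubiquitin ligase gene FBXO32 (0.48). NPTX1 (-2.75), PPP2R2C (-2.70), COL21A1 (-1.65), SYT2 (-1.28) and VAT1L (-1.15) fell most in the authors' deposited table. In the actin list CYR61 and CTGF rose, to 0.30 and 0.38 in the authors' deposited table (adjusted p = 6.52e-04, Fisher's exact test). They were 2 of 18 members, and the median log2 fold of the list was 0.02, so the list as a whole did not move. In the ribosome biogenesis list NOP56 and RRP1B fell, to -0.31 and -0.34 in the authors' deposited table (adjusted p = 0.0135, but 0.0552 against protein-coding genes and 0.708 at a PPDE of 0.99). The separate fit of bound genes did not call NOP56 or CYR61.

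ΔMBIIIa had 16 called genes in the authors' deposited table, 5 risen and 11 fallen, and no list passed. The risen genes in the authors' deposited table were the smooth muscle actin ACTG2 (1.25), the small heat shock gene HSPB7 (1.14), ZFP36 (0.67), NNMT (0.29) and PGM1 (0.21). NPTX1 (-3.36), MAGEA1 (-0.95), LDLRAD4 (-0.83) and CD83 (-0.38) were among the fallen genes in the authors' deposited table. The separate fit of bound genes did not call ZFP36, NNMT, PGM1 or CD83, and at a PPDE of 0.99 there were 9 called genes. MAGEA1 has near-identical relatives on the X chromosome, so its reads may be shared.

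ΔMBIIIb had 36 called genes in the authors' deposited table, 28 risen and 8 fallen, and no list passed. The largest rises in the authors' deposited table were those of MAGEA11 (2.00), also of a multigene family, the metalloprotease ADAMTS9 (1.81), the fibril-associated collagen COL12A1 (1.74), HRAT17 (1.13) and POTEC (0.84). NPTX1 (-2.21), the heparan sulfate enzyme HS6ST2 (-1.50), the glycogen phosphorylase PYGL (-0.80), the noncoding SNHG15 (-0.70) and MATN3 (-0.62) fell most in the authors' deposited table. The separate fit of bound genes did not call SNHG15. No gene of the ribosome biogenesis list was called, and the list's median log2 fold was 0.18.

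NPTX1 and the ribosomal protein-like gene RPL7L1 were called in all 7 comparisons of the authors' deposited table, up in WT and down in each of the 6 mutants. RPL7L1, which falls outside the naming rule and was chosen after its values were seen, stood at 0.50 in WT against EV and between -0.46 in ΔMBII and -0.21 in ΔMB0 and ΔMBIIIa in that table. All 7 comparisons share the WT libraries, so high values in those libraries alone would give these signs. The 7 calls of each gene are therefore not independent.

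The authors' second table lists 9368 genes with a MYC binding site, mapped once in WT cells, and was used to split the calls. In WT against EV 510 of 9165 bound genes rose, or 5.57%, and 244 of 29053 unbound genes, or 0.84% (odds ratio 6.96, adjusted p = 1.18e-143, two-sided Fisher's exact test over 14 tests). Fallen were 6.06% of bound and 1.95% of unbound genes (odds ratio 3.24, adjusted p = 7.46e-78, Fisher's exact test). Many unbound genes are noncoding or hardly expressed. Among protein-coding genes alone the odds ratio was 2.89 for rises (adjusted p = 7.24e-34) and 1.13 for falls (adjusted p = 0.14, Fisher's exact test). In ΔMBII 1.99% of bound and 0.37% of unbound genes fell (odds ratio 5.47, adjusted p = 1.49e-44), and in ΔMBIV 2.43% and 0.36% (odds ratio 6.90, adjusted p = 4.87e-63, Fisher's exact test). Among protein-coding genes these odds ratios were 2.30 (adjusted p = 3.91e-09) and 2.91 (adjusted p = 8.54e-16), and those of ΔMB0 and ΔMBI for falls 3.13 (adjusted p = 2.53e-05) and 2.71 (adjusted p = 0.0452), from Fisher's exact test. Rises of bound genes in the mutants passed in 5 of the 6 over all tested genes and in none over protein-coding genes. Among called genes, the bound ones had risen more often than the unbound ones in WT against EV (odds ratio 2.14, adjusted p = 3.76e-14), and less often in ΔMB0 (odds ratio 0.344, adjusted p = 1.33e-03) and ΔMBII (odds ratio 0.639, adjusted p = 0.0232), by Fisher's exact test over 7 tests. By the same exact test this difference did not pass in ΔMBIV (adjusted p = 0.0856), ΔMBI (0.649), ΔMBIIIa (1) or ΔMBIIIb (1). Genes are not independent replicates, so these p-values describe the genes of these libraries.

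In some mutants the direction of calls also depended on the fit. Over bound genes, the share of called genes that rose was 20% in the all-gene fit and 52.6% in the authors' fit of bound genes alone for ΔMBI, and 27.3% against 50% for ΔMBIIIa. For ΔMBIIIb it was 77.3% against 16.7%, and for ΔMBIV 19.6% against 38.0%. It moved less for ΔMBII (43.1% against 44.6%), WT against EV (47.9% against 53.6%) and ΔMB0 (50.4% against 42.7%). Only 4 called bound genes were shared between the fits in ΔMBI, 1 in ΔMBIIIa and 2 in ΔMBIIIb, whereas 184 were shared in ΔMBII, 128 in ΔMBIV, 76 in ΔMB0 and 976 in WT against EV. The median log2 fold of bound genes moved by at most 0.08 between the fits, in ΔMBIIIb by -0.08 and in ΔMBI by 0.08.

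How much of the WT change each mutant lost was read from those of the 1876 genes called in WT against EV that had a value in the mutant, at least 1873. The median percent of the WT against EV change that was lost was 73.9% in ΔMBII (95% interval over resampled genes 72.8% to 75%), 40.5% in ΔMBIV (38.8% to 42.0%), 38.3% in ΔMB0 (37.5% to 39.3%), 25% in ΔMBI (24% to 26.1%), 20.0% in ΔMBIIIa (19.3% to 21.0%) and 2.55% in ΔMBIIIb (1.22% to 3.88%). The intervals cover the choice of genes only, since the spread between libraries was not used. Over all tested genes, as planned, the slope of the mutant fold on the WT against EV fold was -0.57 in ΔMBII, -0.49 in ΔMBIV, -0.47 in ΔMB0, -0.42 in ΔMBI, -0.39 in ΔMBIIIa and -0.35 in ΔMBIIIb, and with the ΔMBIIIb fold subtracted -0.21, -0.14, -0.11, -0.06 and -0.03 in the first 5 of these. Slopes over the genes called in WT against EV were -0.51 in ΔMBII, -0.42 in ΔMBIV, -0.27 in ΔMB0, -0.21 in ΔMBI, -0.18 in ΔMBIIIa and -0.02 in ΔMBIIIb. A simulated mutant with no loss had a slope of -0.0811 over called genes and a median of 1.22% lost, because the WT libraries are shared, so that slopes and shares of this size cannot be told from no loss. Simulated genes were called with their noise known, unlike in the data, where this bias may be larger. Whether risen or fallen genes lost more depended on the scaling in ΔMBI, ΔMB0 and ΔMBIIIa, while the median over risen genes was higher under each scaling in ΔMBII and ΔMBIV. In ΔMBIV the centred intervals overlapped, at 41.0% to 47.1% over risen and 37.4% to 41.9% over fallen genes. The ΔMBIV slope was steeper over fallen genes, -0.45 against -0.30 as deposited, and no test of the difference was run. In ΔMBI the percent lost was 38.2% over risen and 17.1% over fallen genes as deposited, 20.8% and 29.6% with each comparison centred on its median protein-coding gene, and 48.6% and 6.49% with the ΔMBIIIb fold subtracted. In ΔMB0 it was 38.5% and 37.9% as deposited, 34.9% and 41.8% centred, and 52.5% and 25.9% subtracted, and in ΔMBIIIa 24.1% and 16.6%, 17.6% and 22.1%, and 36.9% and 6.05%. In ΔMBIIIb, whose pooled median hides this, it was -12.8% over risen and 11.3% over fallen genes as deposited, and -0.504% and 1.28% centred, so that pairs with its fold subtracted carry its own offset. In ΔMBIV these pairs were 55.3% and 32%, 43.9% and 39.4%, and 65.9% and 22.6%, and in ΔMBII 77.1% and 72.2%, 77.5% and 71.0%, and 88.6% and 60.5%.

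**Figure D3:**
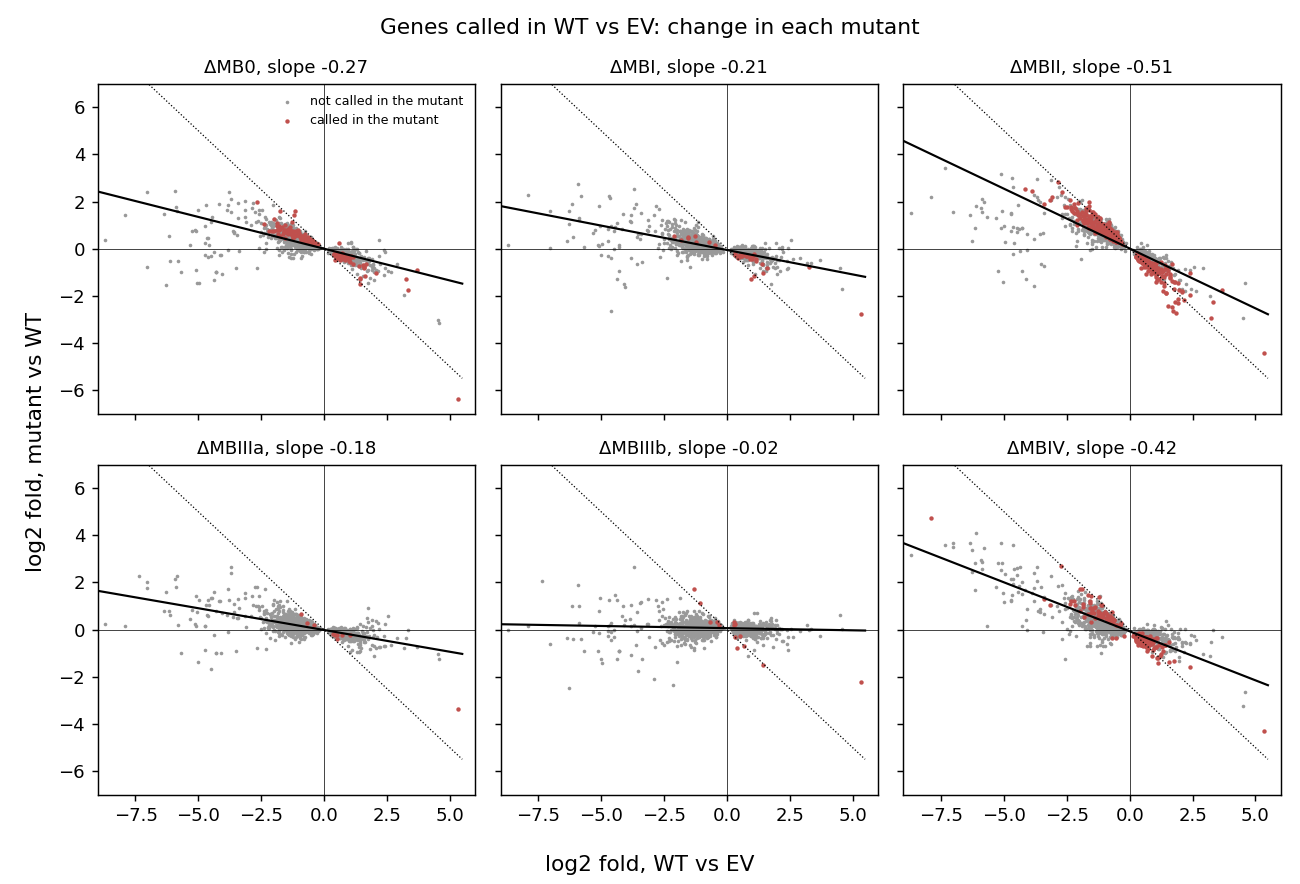
Log2 fold of each mutant against WT (vertical) over the log2 fold of WT against EV (horizontal) for the genes called in WT against EV, with genes also called in the mutant in red. The solid line is the fitted slope, from -0.51 in ΔMBII to -0.02 in ΔMBIIIb, and the dotted line marks a full return to the EV level.

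Mutant and WT comparisons share the WT libraries, which alone correlates their folds across genes. Over all genes tested in both comparisons and in ΔMBIIIb, Pearson's r across genes with WT against EV was -0.58 in ΔMBII, -0.52 in ΔMB0, -0.51 in ΔMBIV, -0.45 in ΔMBI, -0.43 in ΔMBIIIa and -0.40 in ΔMBIIIb. Simulated groups with no effect and the same shared libraries gave between -0.51 and -0.49. The observed covariance was -0.365 against a simulated -0.264 in ΔMBII, a difference of -0.101, and the differences were -0.0537 in ΔMBIV, -0.0337 in ΔMB0, -0.00163 in ΔMBI, 0.0142 in ΔMBIIIa and 0.0401 in ΔMBIIIb. The simulated noise was taken from the ΔMBIIIb folds and is too large where these hold effects. Subtracting the ΔMBIIIb fold removes the WT libraries from the mutant side, and the median percent lost was then 69.2% in ΔMBII, 34.8% in ΔMBIV, 34.9% in ΔMB0, 20.5% in ΔMBI and 16% in ΔMBIIIa.

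Called genes overlapped in the same way. Of the 554 genes called in ΔMBII, 449 were also called in WT against EV, all in the opposite direction, and so were 35 of 45 in ΔMBI and 10 of 16 in ΔMBIIIa. In ΔMBIV 252 of 420 were called in the opposite direction and 3 in the same, in ΔMB0 179 of 214 and 1, and in ΔMBIIIb 11 of 36 and 3. Independent lists would share 8.06 risen and 5.92 fallen genes with WT against EV in ΔMBII, where 224 and 225 were shared. ΔMBII and ΔMBIV shared 40 risen and 98 fallen genes, against 0.684 and 2.56 for independent lists, and ΔMBII and ΔMB0 shared 56 and 51, against 0.932 and 0.659. As many top genes, drawn from simulated groups with no effect and shared WT libraries, overlapped by 77.3 risen and 65.1 fallen between ΔMBII and WT against EV, by 13.9 and 37.1 between ΔMBII and ΔMBIV, and by 18.6 and 13.7 between ΔMBII and ΔMB0. With WT against EV, ΔMBIV shared 71 risen and 181 fallen genes against a simulated 33.6 and 69.3. For ΔMB0 these were 108 and 71 against 42.9 and 24.8, and for ΔMBI 8 and 27 against 4.99 and 12.2. ΔMBIIIa shared 3 and 7 against 2.65 and 4.59, and ΔMBIIIb 5 and 6 against 12.4 and 3.15. Part of the excesses may come from the shared WT libraries. In ΔMBIIIa the overlap was near the simulated one, and in ΔMBIIIb that of risen genes was below it. The simulated noise came from the ΔMBIIIb folds, and simulated genes were not called by PPDE. The simulated counts therefore do not settle what the shared libraries alone would give. Whether mutants differ from each other gene by gene was not tested, and comparisons of mutants with EV were not used for these overlaps.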

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

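The comparisons with protein-coding genes, with the authors' fit of bound genes, and every alternative for the percent of the WT change lost were chosen after the data were seen, and the others before. The number of called genes stayed within 1.5 times at a PPDE of 0.90 and among protein-coding genes in all 7 comparisons, and at a PPDE of 0.99 in 6, the exception being ΔMBIIIa with 9 called genes. Asking for an absolute log2 fold of at least 1 as well, which can only remove genes, left 608 in WT against EV, 23 in ΔMB0, 7 in ΔMBI, 160 in ΔMBII, 3 in ΔMBIIIa, 7 in ΔMBIIIb and 47 in ΔMBIV. The authors' fit of bound genes alone called 213 bound genes in ΔMB0, 19 in ΔMBI, 6 in ΔMBIIIa and 12 in ΔMBIIIb, outside 1.5 times the all-gene fit.

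Of 29 list tests past the threshold, 29 kept their side of it at a PPDE of 0.90, 22 at 0.99 and 21 with protein-coding genes as background. For ribosomal proteins among fallen genes in ΔMBII no member was left at a PPDE of 0.99, so the adjusted p was 1 by construction. Over-represented lists numbered 1 in ΔMB0 with protein-coding genes as background, and 1 in ΔMBI both with that background and at a PPDE of 0.99. Among protein-coding genes only, the odds ratio of bound against unbound genes no longer passed for risen genes in ΔMB0 (1.02), ΔMBI (1.48), ΔMBII (1.25), ΔMBIIIb (2.08) and ΔMBIV (1.51), nor for fallen genes in ΔMBIIIa (2.63), ΔMBIIIb (1.31) and WT against EV (1.13). At a PPDE of 0.90 it no longer passed for risen genes in ΔMBI (3.15). Of the named bound genes, 102 calls were kept in the fit of bound genes and 35 were lost, and the cause was not tested for these list, odds ratio and gene results.

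The slope on WT against EV over all tested genes moved when taken over the genes called in WT against EV, to -0.27 in ΔMB0, -0.21 in ΔMBI, -0.51 in ΔMBII, -0.18 in ΔMBIIIa, -0.0184 in ΔMBIIIb and -0.42 in ΔMBIV. Over bound genes it was -0.40 in ΔMB0, -0.30 in ΔMBI, -0.65 in ΔMBII, -0.28 in ΔMBIIIa, -0.13 in ΔMBIIIb and -0.45 in ΔMBIV. The median percent of the WT change lost, with the ΔMBIIIb fold subtracted, was 34.9% in ΔMB0, 20.5% in ΔMBI, 69.2% in ΔMBII, 16% in ΔMBIIIa and 34.8% in ΔMBIV. Over bound genes only it was 26.5% in ΔMBI, 75.4% in ΔMBII, 21.0% in ΔMBIIIa, 0.326% in ΔMBIIIb and 42.9% in ΔMBIV, and with centred folds it left its interval in ΔMBIIIb alone, at 0.315%. For these shifts the cause was not tested.

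No paired analysis was possible because the deposited tables hold comparisons of groups and no value carries a replicate number. For the same reason other size factors, tools, filters and pseudocounts, and leaving out a replicate, were not run. Neither were a Bonferroni adjustment, which needs unadjusted p-values, and a limit to the upper part of genes by mean expression. What depth limits is unknown, as depths were not used here.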

Other observations

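All tests in this part were chosen after the results were seen. Of 15 gene families examined beside the lists, several held more called genes than others in WT against EV. Of 77 mitochondrial ribosomal protein genes 21 rose and none fell (adjusted p = 3.56e-16, two-sided Fisher's exact test over all families and comparisons), and 13 fell in ΔMBIV (adjusted p = 1.30e-11) and 7 in ΔMBII (adjusted p = 5.38e-05). Host genes of small nucleolar RNAs rose in 9 of 22 cases (adjusted p = 8.97e-09, Fisher's exact test), and subunits of RNA polymerases I and III, which make ribosomal and transfer RNA, in 6 of 15 (adjusted p = 7.46e-06). Of the clustered beta protocadherins, neuronal adhesion genes with near-identical copies whose reads are uncertain, 8 of 16 fell (adjusted p = 2.36e-07, Fisher's exact test). Desmosomal cadherins fell in 4 of 6 cases (adjusted p = 1.85e-04, Fisher's exact test), and laminins, of the basement membrane, in 4 of 12 (adjusted p = 3.74e-03). Collagens (13 of 39, adjusted p = 3.15e-09), integrins (10 of 31, 4.05e-07) and serpins B (5 of 10, 1.12e-04) fell as well, by the same exact test. Small nucleolar RNAs rose in 13 of 156 cases (2.35e-04, same exact test). This family contains the SNORD116 cluster of near-identical copies, of which 6 of 25 rose (1.56e-04, same exact test). Those 6 genes are among the 13, so these results are not independent. Nucleoporins (none called of 20), semaphorins (1 risen and 1 fallen of 20), keratins (2 fallen of 32, adjusted p = 1) and exosome components (2 risen of 10, adjusted p = 0.116) did not pass in WT against EV by Fisher's exact test. In ΔMBII 2 of 10 exosome components fell (adjusted p = 0.026, Fisher's exact test). By the same exact test, 4 of 25 SNORD116 genes (5.42e-04) and 3 of 23 snoRNA host genes (7.97e-03) fell in ΔMBII. Risen there were 5 of 40 collagens (1.61e-04) and 2 of 12 laminins (0.0304). Some host genes also fell in ΔMB0 (2 of 22, 0.0118) and ΔMBI (2 of 22, 2.33e-03), and SNORD116 genes in ΔMBIV (4 of 25, 8.23e-04). In ΔMBIIIb the host gene result (1 of 21, 0.0425, same exact test) rested on SNHG15 alone. The family's median log2 fold there was 0.07, and the separate fit of bound genes did not call SNHG15.

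A block of neighbouring globin and olfactory receptor genes on chromosome 11 was higher in WT than in EV and lower in ΔMBII than in WT, and its median was below 0 in ΔMB0 as well. The annotated HBE1 gene (GENCODE 29, GRCh38) spans 16 tested genes, of which 10 were called in WT against EV, with a median log2 fold of 1.74, on the plus strand of 1.73 and on the minus strand of 1.75. Their median exceeded that of the 10 tested genes on each side by 1.82, and in the mutants against WT it was -2.08 in ΔMBII with 10 called, -0.85 in ΔMB0 with none called, -0.44 in ΔMBI, -0.47 in ΔMBIV, 0.23 in ΔMBIIIa and 0.07 in ΔMBIIIb. However, the flanking folds went both ways. Of those 20 genes 4, none of them called, lay within the range of folds inside, so that the ends of the change were not settled. Among them were HBG1, BGLT3 and HBBP1, the next tested genes beside HBE1, at 1.35, 1.88 and 1.41. In ΔMBII they stood at -1.21, -1.82 and -1.87, so the change may run past the annotated gene on that side. Beyond them HBD stood at -0.69 in WT against EV. On the other side the nearest tested gene, UBQLNL, stood at -1.32, and OR52T1P at 1.89. The flanking median against WT was 0.05 in ΔMBII, -0.03 in ΔMB0 and ΔMBIIIa, -0.02 in ΔMBIV and -0.19 in ΔMBIIIb. In ΔMBI it was -0.53, lower than inside, so the ΔMBI median does not set the block apart. In ΔMBI and in ΔMBIV 11 of 20 flanking genes lay within the range inside. Reads of a single long transcript counted over the genes it overlaps cannot be told apart from a change of the whole region, and reads shared between near-identical receptors were not tested.

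In WT against EV 62 genes fell by at least 3 on the log2 scale, with epithelial genes such as KRT5, KRT14 and CDH1 among them. Cells of another type in the EV libraries alone would leave these genes alike in ΔMBIV and ΔMBIIIb, but the median ΔMBIV fold minus the ΔMBIIIb fold was 1.88, with a lower quartile of 0.92. Such cells in the EV and ΔMBIV libraries would leave them alike in ΔMBII and ΔMBIIIb, but that median difference was 1.47 (lower quartile 0.36, 46 genes above 0), and it was 0.66 in ΔMBI, 0.52 in ΔMB0 and 0.41 in ΔMBIIIa. Such cells at differing shares in EV and several mutants cannot be told apart from a change in the cells themselves, since values per library were not used here and the interquartile range of ΔMBIV against EV, taken as the sum of the ΔMBIV and the WT against EV fold, was 1.22. Repression that depends on MYC stays open as well. Of the 62 genes, 41 shared their exact ΔMBIIIb fold with another gene. This can happen where reads are few, so these folds may depend on the model. Over the 18 with no shared ΔMBIIIb fold, the median ΔMBII fold minus the ΔMBIIIb fold was 1.57, with 17 above 0.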
